A study of Mus musculus with 7 samples.

How the data were processed

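RNA bound to tagged ribosomes was sequenced from kisspeptin cells of the anteroventral periventricular nucleus (AVPV), a preoptic cell group that releases kisspeptin, of female C57BL/6 mice. In these mice the ribosomal protein Rpl22 carries an HA tag in cells with Kiss1-driven Cre recombinase, and the tagged ribosomes were pulled down from micropunches with an antibody to the tag. Per the labels, each library came from a pool of 4 brains. The 4 GDX libraries came from ovariectomized females without estradiol, and the 3 E2 libraries came from ovariectomized females given estradiol. The libraries were made from polyadenylated RNA without strand information and sequenced on an Illumina instrument.

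The deposited table held 1 expected count per gene and library, and 33.1% of its non-zero values were not whole numbers, where any decimal part counted, with no tolerance. Trimmomatic 0.38, STAR 2.6.0a, RSEM 1.3.0 and the mouse build mm10 were used by the authors per the submitters' processing notes, which did not state their roles or order, and the gene annotation was not given in the sources used here. Gene identifiers were matched to GENCODE vM21 on GRCm38 for symbols and coordinates, and 55203 of 55384 listed genes matched. No raw reads were used here, so strand and read placement could not be examined. RNA encoded by the mitochondrial genome was not analysed here.

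Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors. Genes were kept by filterByExpr with a minimum count of 10, a minimum total of 15 and a smallest group of 3, which left 18282 genes for testing. E2 was compared with GDX by the edgeR quasi-likelihood test with robust dispersions. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Levels are CPM, counts scaled by edgeR to library size, with the SD between libraries, and log2 fold changes, E2 over GDX, have their standard error and use a prior count of 0.125. Since every library was a pool, the p-values measure spread between pools, not between single animals.

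Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, over lists with at least 5 tested genes, and again with the correlation estimated from the libraries and with fry. Members of each list were counted both over all genes tested and adjusted over the list alone. Marker lists of other cell types and neighbouring nuclei were scored as mean log2 CPM with a prior count of 2, and the groups were compared by a two-sided exact permutation test over all 35 splits of the 7 libraries, whose smallest possible p is 0.0286. The mean over all astrocyte, oligodendrocyte, microglial and endothelial markers made the non-neuronal score that was used as a covariate. The floor of 3 counts corresponded to 0.0818 to 0.101 CPM across libraries, and this floor covers counting error only.

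The comparison, its test, the gene lists, the marker lists, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule took Kiss1, Rpl22, Esr1, Pgr and Th. It also took the 12 largest rises and the 12 largest falls among changed genes with a mean of at least 5 CPM and groups that did not overlap, leaving out symbols of predicted genes. From every list it took up to 4 changed members with the largest change and the first 2 members that did not pass. Genes outside this rule are named as chosen after their values were seen.

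Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, no filter or a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, dispersions without the robust option, the replicate number as a block, a score of non-neuronal markers as a covariate, an adjusted p under 0.01, and leaving out each library in turn. Leaving out GDX replicates 1 and 4 together, using library sizes without scaling factors, and adding the counts of Kiss1 to those of an overlapping gene were chosen after the data were seen. Checked on simulated data with planted changes, edgeR recovered 58.2% of 2-fold and 79.8% of 4-fold changes, and 12.7% of its calls were false, above the 5% aimed at, against 23.5% for DESeq2 and 11.5% for limma-voom.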

Results

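Ribosome-bound RNA of AVPV kisspeptin cells was measured in 7 libraries, 4 from ovariectomized females (GDX) and 3 from ovariectomized females given estradiol (E2). The 4 GDX libraries held totals of 35825341, 29207544, 36213127 and 35084629 counts, and the 3 E2 libraries held 33438199, 31055366 and 30929883. Log2 levels correlated across genes with Pearson's r of 0.964 to 0.976 within groups and 0.954 to 0.97 between groups, where genes are not independent replicates. GDX replicates 2 and 3 correlated less with GDX replicate 4 (0.965 and 0.964) than with E2 replicate 1 (0.968 and 0.97). Protein-coding genes held 97.2% of the counts of GDX replicate 4 and 94.86% to 95.67% elsewhere, and mitochondrial pseudogenes on chromosome 1 held 0.656% there and 1.39% to 2.26% elsewhere. The comparison addresses, per the series design, how estradiol changes the translated RNA of these cells.

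With estradiol, Kiss1, which encodes kisspeptin and drives the Cre that marks these cells, rose from 66.5 ± 31.7 CPM (SD, n = 4) to 415 ± 60.8 CPM (SD, n = 3), a 6.24-fold rise. The peptide gene Nmb (neuromedin B) rose 48.2-fold, from 4.55 ± 0.352 to 219 ± 29.1 CPM. The ghrelin receptor gene Ghsr rose 9.64-fold, from 4.58 ± 0.714 to 44.2 ± 7.32 CPM. Slc17a8, which encodes the vesicular glutamate transporter VGLUT3, was 9.83-fold higher in GDX and fell from 48.3 ± 4.81 to 4.92 ± 0.267 CPM. Npy2r, a receptor for neuropeptide Y, was 8.01-fold higher in GDX and fell from 141 ± 24.2 to 17.6 ± 1.61 CPM, with the same n as for Kiss1.

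Of 18282 genes tested, 710 changed (3.88%), of which 467 rose and 243 fell in E2. At least 2-fold changes were found for 134 rises and 78 falls, and at least 4-fold changes for 56 and 24. Protein-coding genes made up 453 of the rises and 237 of the falls. The levels of all 710 genes did not overlap between the groups, as for 16.5% of all tested genes, where chance gives 5.71%. The share of rises among changed genes was 65.8%, against 48.2% with the DESeq2 Wald test, 44.9% without a low-count filter and 52.2% with library sizes alone, a scaling chosen after the data were seen. Left-out libraries moved the counts to 268 rises and 96 falls without E2 replicate 1, to 311 and 107 without E2 replicate 2, to 135 falls without E2 replicate 3, to 154 falls without GDX replicate 1 and to 428 falls without GDX replicate 3. With the score of non-neuronal markers as a covariate 221 genes rose and 94 fell, DESeq2 gave 675 and 725, and limma-voom gave 710 and 399. That score was 5.06 to 5.73 in the GDX and 4.83 to 5.04 in the E2 libraries. It did not overlap between the groups and is thus partly confounded with treatment. A call lost with the covariate therefore does not show that non-neuronal RNA was its cause.

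The Kiss1 gene (ENSMUSG00000116158, chromosome 1, 133321875 to 133329901, GRCm38) had a log2 fold change of 2.64 ± 0.36 and an adjusted p of 0.0158. GDX replicate 4 held 113.5 CPM, and the other GDX libraries 44.5 to 56.0 CPM. The annotation places Gm28040 (ENSMUSG00000115958) over the same locus, on the same strand, where it covers exon 2 of Kiss1 and 367 bp of exon 3, so the division of counts between them is uncertain. A second identifier of the name Gm28040, which did not pass the filter, covers both exons and exon 1 of Kiss1 in full, and its counts are in the sum below. Golt1a, which did not pass the filter either, shares 102 bp with Kiss1 on the same strand. Gm28040 was examined after its values were seen, and it rose from 118 ± 67.9 to 1129 ± 97.6 CPM (adjusted p = 0.0167). Kiss1 held 24.4% to 42.5% of the summed counts. Gm28040 rose more than Kiss1, by a log2 fold change of 3.26. The share of Kiss1 was therefore lower in each E2 library than in any GDX library, and the fold change of Kiss1 alone depends on this division. The sum rose from 184.8 ± 98.7 to 1544 ± 142 CPM, 8.36-fold, with a log2 fold change of 3.06 ± 0.40 and an adjusted p of 0.0148. The Kiss1 call was lost without GDX replicate 1 (log2 fold change 2.54, adjusted p = 0.0575), without E2 replicate 1 (2.70, 0.0574), without E2 replicate 2 (2.52, 0.0593) and with the covariate (3.04, 0.145). Over all alternatives its log2 fold change ranged from 2.49 to 3.04 and its adjusted p from 3.81e-10 to 0.145, and the sum lost its call in the same 4 fits, with adjusted p values of 0.0523, 0.0611, 0.0573 and 0.15.

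**Figure D1:**
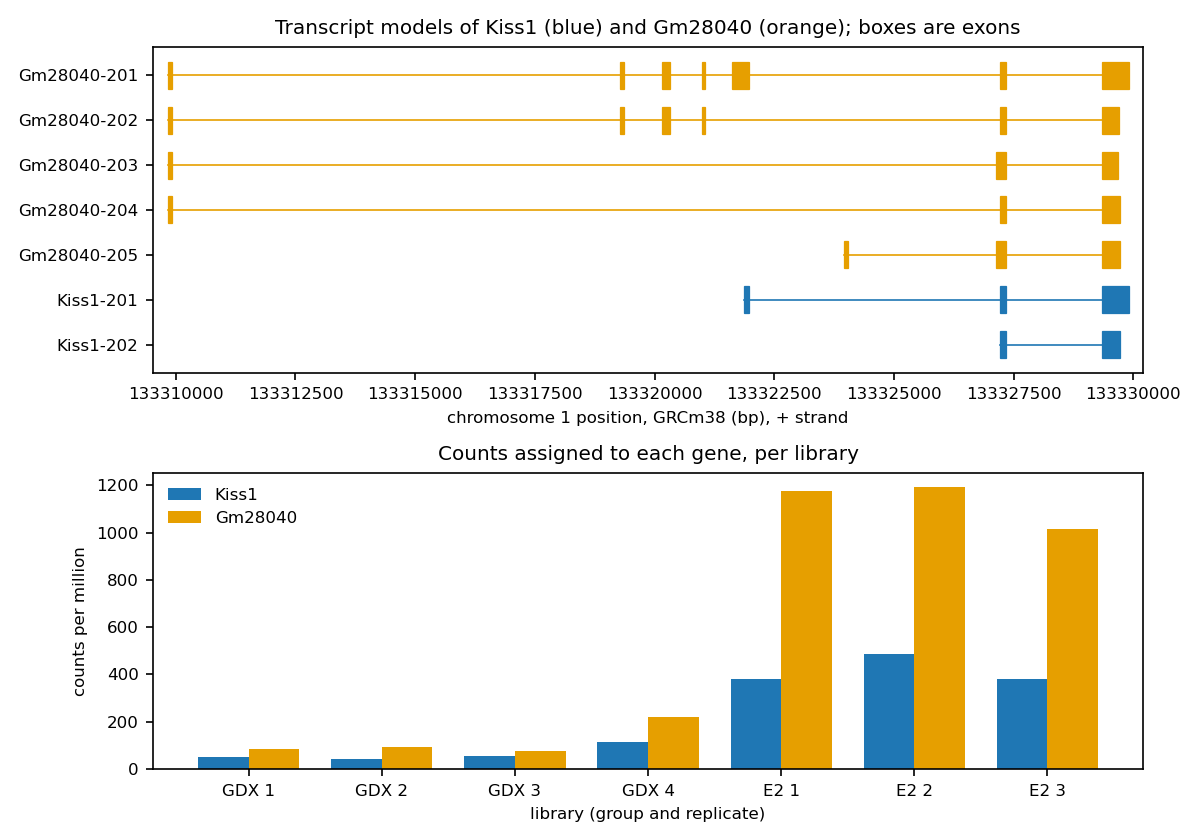
The upper panel maps annotated exons (boxes) of Kiss1 and Gm28040 transcripts along chromosome 1 (base pairs, GRCm38), and the lower panel gives the CPM counted to each gene in every library (bars). The E2 libraries hold 379 to 485 CPM for Kiss1 and 1016 to 1193 CPM for Gm28040, and GDX replicate 4 holds 113.5 and 219 CPM, above the other GDX libraries.

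Further large rises were seen in genes of several kinds. Aqp5, a water channel gene, rose from 0.762 to 29.1 CPM (log2 fold change 5.25 ± 0.22). C1ql2, which encodes a secreted synapse-organising protein, rose from 13.8 ± 2.43 to 366 ± 50.6 CPM (4.73 ± 0.15). Creb3l1, a transcription factor gene of the endoplasmic reticulum membrane, rose from 9.77 to 91.8 CPM (3.23 ± 0.11). Sytl4, whose product granuphilin binds secretory granules, rose from 17 to 157 CPM (3.21 ± 0.11). The orexin receptor gene Hcrtr1 rose from 2.84 to 24.2 CPM (3.09 ± 0.19), and Pth2r, a parathyroid hormone receptor gene, from 2.06 to 12.4 CPM (2.59 ± 0.20). Rasd1, a Ras-like GTPase gene, rose from 14.1 to 84.8 CPM, and the interleukin receptor gene Il10ra from 3.47 to 17.5 CPM. Map3k15, a kinase gene, rose from 10.6 to 62.0 CPM, and it overlaps Pdha1 over 425 bp on the opposite strand, so its value is uncertain in unstranded libraries. Nmb shares 163 bp with Sec11a on the same strand, which also leaves its value uncertain. Adjusted p values of the 12 largest rises lay between 2.27e-10 for Nmb and 0.0158 for Kiss1.

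The largest falls also included Bpifb1, a secreted lipid-binding protein gene, from 10.3 to 2.03 CPM (log2 fold change −2.34 ± 0.25). Mxra7, a gene of a membrane protein, fell from 54.9 to 13.2 CPM (−2.06 ± 0.11). The orphan receptor gene Brs3 fell from 12.1 to 2.96 CPM (−2.04 ± 0.23), and Pgr15l, another orphan receptor gene, from 59.1 to 16.1 CPM (−1.88 ± 0.13). Sox3, a transcription factor gene on the X chromosome, fell from 61.7 to 15.3 CPM (−2.01 ± 0.17). Pcdhac1, a protocadherin gene, fell from 10.8 to 2.76 CPM, and 2712 bp of its exons are shared with other Pcdha genes, which leaves its value uncertain. Fzd7, a frizzled receptor gene, fell from 11.9 to 3.80 CPM, and Nkd1 from 30.9 to 10.2 CPM. Thsd7b fell from 49.5 to 17.1 CPM. Fbln2, an extracellular matrix gene, fell from 12.5 to 4.72 CPM (−1.41 ± 0.29, adjusted p = 0.0187). Its call was lost without GDX replicate 2 (adjusted p = 0.0508), E2 replicate 1 (0.0954) or E2 replicate 3 (0.0954) and with the covariate (0.3), as was the Fzd7 call with the covariate (0.0517). The other 11 falls had adjusted p values from 5.15e-08 for Slc17a8 to 0.0028 for Fzd7.

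**Figure D2:**
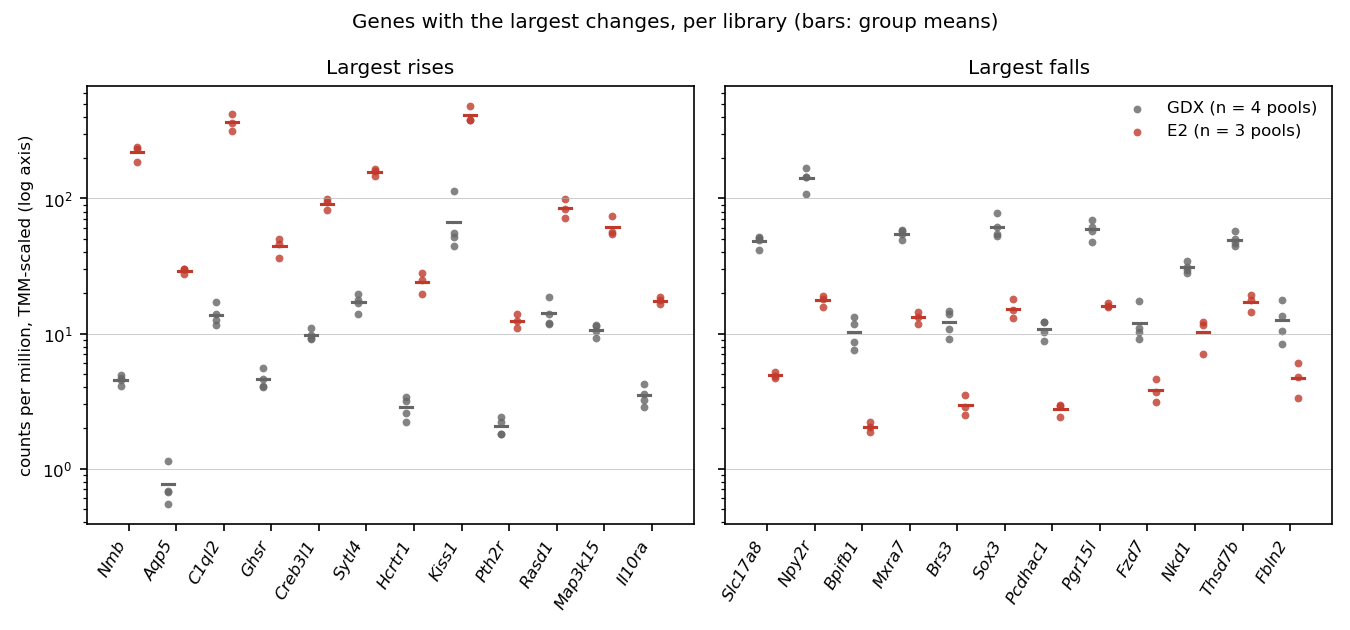
CPM (log axis) of the 12 largest rises and the 12 largest falls under the naming rule, with 1 point per library for 4 GDX and 3 E2 libraries and a bar at each group mean. The groups do not overlap for any of these genes, as the rule requires, and Nmb goes from a mean of 4.55 to 219 CPM and Slc17a8 from 48.3 to 4.92 CPM.

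The progesterone receptor gene Pgr, a classic estrogen target, rose from 28.3 ± 3.95 to 117 ± 12.9 CPM (log2 fold change 2.05 ± 0.12, adjusted p = 1.42e-06). Th, which encodes the rate-limiting enzyme of dopamine synthesis, rose from 297 ± 43.8 to 551 ± 18.3 CPM (0.89 ± 0.11, adjusted p = 0.000506). Esr1, the gene of estrogen receptor alpha, was 255 ± 36.8 CPM in GDX and 194 ± 16.8 CPM in E2, and its log2 fold change of −0.39 ± 0.11 did not pass (adjusted p = 0.0901). Rpl22, the tagged gene, was 30.7 CPM in GDX and 34.5 CPM in E2 (0.17 ± 0.10, adjusted p = 0.451).

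Of 18 tested genes of the AVPV kisspeptin phenotype, 9 rose, 3 fell and 6 did not pass. Adjusted over the list alone 11 rose and 4 fell. The 3 falls went to 1 without GDX replicate 2 or 4 or E2 replicate 2 or 3, and to 4 without GDX replicate 1. Nts (neurotensin) rose from 90.3 to 340 CPM and Gad2, which makes GABA, from 728 to 983 CPM. Camera gave this list an adjusted p of 3.11e-12, and adjusted p = 0.143 with an estimated correlation. Of 20 textbook estrogen-responsive genes, 10 rose and none fell, and adjusted over the list alone 11 rose and 1 fell. Cckar, a cholecystokinin receptor gene, rose from 6.55 to 27.8 CPM, Nrip1, a nuclear receptor corepressor gene, from 16.6 to 52.8 CPM, and Greb1 from 2.74 to 9.98 CPM, where Greb1 lost its call with the covariate (adjusted p = 0.0537). Igfbp4, also on this list, did not pass at a log2 fold change of −0.86 (adjusted p = 0.403). The camera adjusted p was 2.28e-13, and adjusted p = 0.143 with an estimated correlation.

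Of 40 tested neuropeptide genes 12 rose, 1 fell and 27 did not pass, or 13 rose and 1 fell adjusted over the list alone. Camera placed the list higher with an adjusted p of 1.1e-15, and adjusted p = 0.143 with an estimated correlation. Cartpt rose from 109 to 263 CPM, Prok2 (prokineticin 2) from 5.21 to 23.8 CPM and Grp (gastrin-releasing peptide) from 5.83 to 14.3 CPM. Agrp rose from 0.277 to 3.03 CPM, a low level, and it overlaps Ctcf over 114 bp on the opposite strand and Gm5914 (1.75 and 1.80 CPM) over 114 bp on its own strand, so its level is uncertain. Penk was not called at a log2 fold change of 0.40 (adjusted p = 0.0727). Among 27 genes of peptide processing and dense-core granules 6 rose and none fell, or 8 and 2 adjusted over the list alone. The granin genes Scg2 and Vgf rose from 3591 to 6106 and from 769 to 1209 CPM, and the granule membrane gene Ptprn from 1054 to 1496 CPM. The median log2 fold change of this list was 0.156, near the 0.153 of the pan-neuronal marker list. Camera gave this list of granule genes an adjusted p of 0.00153, and adjusted p = 0.497 with an estimated correlation. That call was lost with the non-neuronal covariate (adjusted p = 0.114), and the count of 6 went to 3 without GDX replicate 1 or 2 or E2 replicate 1. Peptide hormone receptor genes went both ways, with 8 of 55 higher and 6 lower, or 9 and 12 adjusted over the list alone (camera adjusted p = 0.651).

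Genes of dopamine synthesis and transport included 3 of 18 that rose and 1 that fell, or 4 and 2 adjusted over the list alone. Maob, which degrades dopamine, rose from 37.9 to 187 CPM, and Pts, a gene of cofactor synthesis, from 21.2 to 36.6 CPM. Slc18a2, the vesicular monoamine transporter gene, fell (log2 fold change −0.57), a call lost without GDX replicate 2, 3 or 4 or E2 replicate 2 or 3, with adjusted p values of 0.0568 to 0.156. The camera adjusted p was 0.0444, and adjusted p = 0.497 with an estimated correlation, and the list's median of −0.0637 differed in sign from its mean of 0.128. That call was lost without GDX replicate 1 (0.0573), 2 (0.0664) or 4 (0.0686) or E2 replicate 2 (0.124), and the median turned to 0.0227 without E2 replicate 1. Of 30 genes of glutamate transport and receptors 2 rose and 3 fell, or 4 and 7 adjusted over the list alone, with Grm2 falling from 19 to 7.85 CPM beside Slc17a8. Slc17a6, the gene of VGLUT2, did not pass at a log2 fold change of 0.14 (adjusted p = 0.58). Camera gave a lower level with an adjusted p of 0.0337, and adjusted p = 0.66 with an estimated correlation, where the median of 0.0257 differed in sign from the mean of −0.149. That call was lost without GDX replicate 2 (0.0922) or 4 (0.0613) or E2 replicate 2 (0.0696), and the median turned negative without GDX replicate 4 (−0.0168), E2 replicate 1 (−0.0119) or E2 replicate 3 (−0.00758). The list of GABA synthesis and transport had 2 of 14 genes higher and 1 lower, or 3 and 1 adjusted over the list alone. The 2 higher were Gad2 and Dlx2, a transcription factor gene that lost its call with the covariate (adjusted p = 0.116). GABA and glycine receptors had none of 21 higher and 2 lower, or none and 4. Neither list passed camera, with adjusted p values of 0.33 and 0.126. The 5 changed glutamate genes went to 3 without GDX replicate 1 or 2 or any E2 replicate, and the 2 GABA and glycine receptor genes to 1 without GDX replicate 2 or any E2 replicate.

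Among ion channels, 5 of 55 potassium and HCN channel genes rose and none fell, or 8 and 3 adjusted over the list alone. The pacemaker channel gene Hcn4 rose by a log2 fold change of 0.73, and Hcn2 did not pass at −0.05. Of 17 TRP channel and store-operated calcium entry genes 3 rose, or 4 with 1 fall adjusted over the list alone. Calcium channels had 3 of 20 genes higher and 1 lower, the auxiliary subunit gene Cacng5 (−0.81), or 6 and 2 adjusted over the list alone. Of 12 sodium channel genes 1 rose by either count. The camera adjusted p values of these lists were 0.517, 0.207, 0.135 and 0.599, so none passed. Without E2 replicate 1 the changed genes went from 5 to 2 for potassium and HCN channels, from 3 to 1 for TRP channels, from 4 to 2 for calcium channels and from 1 to 0 for sodium channels.

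Steroid receptors and coregulators had 6 of 30 genes higher and 3 lower, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.207). Circadian clock genes had 2 of 26 higher and 2 lower, or 3 and 5 adjusted over the list alone (0.986). Of these 4, Per2, Nr1d1 and Dbp lost their calls without E2 replicate 1 (adjusted p = 0.0909, 0.0761 and 0.138), and each also without 1 or 2 other libraries. On the opposite strand Nr1d1 overlaps Thra (570.5 and 454 CPM) over 263 bp, and Dbp overlaps Sphk2 (33.6 and 36.5 CPM) over 539 bp. The values of Nr1d1 and Dbp are therefore uncertain in unstranded libraries. Npas2, a partner of the core clock gene Arntl, rose from 7.41 to 21.5 CPM, where Clock did not pass at a log2 fold change of 0.09. Of 28 immediate early genes 3 rose and 1 fell, or 4 and 4 (0.651). Among these, Fosl2 rose from 15.9 to 31.7 CPM, and Fos rose by 0.92, a call lost without E2 replicate 1 (adjusted p = 0.102), 2 (0.076) or 3 (0.0753). RGS and GRK genes had 1 of 21 higher and 2 lower, or 2 and 2 (0.207), with Rgs2 lower by a log2 fold change of −0.66. Of 49 genes on the hypothalamic transcription factor list 1 rose and 3 fell by either count (0.274), and Hmx3 fell from 28.5 to 12.1 CPM. The 1 that rose, Moxd1 (log2 fold change 1.27), encodes a monooxygenase and not a transcription factor. Its call was lost without E2 replicate 1, 2 or 3 (adjusted p = 0.0658 to 0.0889). Synaptic vesicle genes had 3 of 45 higher and 3 lower, or 4 and 3 (0.741), with Syt2, a calcium sensor gene, higher by 1.16. Axon guidance and adhesion genes had 7 of 70 higher and 4 lower, or 9 and 10 (0.651). Sema5a was higher by 0.97, Nrp1 by 0.81 and Flrt3 lower, from 55.5 to 22.3 CPM. Without GDX replicate 3 this list had 8 genes higher and 8 lower. Of 25 insulin and IGF signalling genes 1 rose, or 2 adjusted over the list alone (0.774), which was Irs2 with a log2 fold change of 0.65. With 1 library left out, the 4 changed immediate early genes went to 2 without any E2 replicate and to 7 without GDX replicate 3, the 6 synaptic vesicle genes to 2 without E2 replicate 3 and 9 without GDX replicate 4, and the 1 insulin and IGF gene to 3 without GDX replicate 4. The 4 changed genes of the transcription factor list went to 1 without E2 replicate 1 or 2. The 3 RGS and GRK genes went to 1 without GDX replicate 2 or E2 replicate 1 or 2.

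Of 25 cholesterol genes 2 rose by either count (camera adjusted p = 0.191), Dhcr7 and Insig1, and Dhcr7 lost its call without E2 replicate 3 (adjusted p = 0.0533) and Insig1 without E2 replicate 1 (0.0739) or 2 (0.0799). Of 33 unfolded protein response genes 1 rose, or 1 with 1 fall adjusted over the list alone (0.995), and Hspa5 did not pass at a log2 fold change of 0.01. Of 15 heat shock genes 1 rose, or 2 and 2 adjusted over the list alone (0.33). No edgeR call was made among 33 chromatin regulator genes (0.518), of which 1 rose and 1 fell adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 and limma-voom each called 2. Interferon and MHC class I genes were lower as a list, with 1 of 25 lower by either count (0.00167, and adjusted p = 0.692 with an estimated correlation), and the endothelial and astrocyte marker lists were lower beside it, by −0.85 and −0.58. No member changed among 78 cytosolic ribosomal protein genes and 79 genes of oxidative phosphorylation by either count, and camera placed both lists higher, with adjusted p values of 0.0146 and 0.0444, and adjusted p = 0.847 for each with an estimated correlation. In each of these lists edgeR gave 3 genes an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1. Both lists turned to lower medians with the covariate, at log2 fold changes of −0.103 and −0.0316. There camera placed the ribosomal list lower (adjusted p = 0.035), and oxidative phosphorylation did not pass (0.447). The ribosomal call was lost without GDX replicate 4 (0.825) or E2 replicate 2 (0.0696), and the oxidative phosphorylation call without GDX replicate 1 (0.126), 2 (0.19) or 4 (0.481) or E2 replicate 2 (0.491). Over the 28 biology lists, 74 of 886 distinct genes rose and 34 fell, a total that dropped to 61 without E2 replicate 1 and 71 without E2 replicate 3. In 20 of the 28 lists leaving out 1 library moved the count by over 1.5 times, among them heat shock genes, from 1 to 3 without GDX replicate 4 and 0 without E2 replicate 1, and the interferon and unfolded protein response lists, from 1 to 2 without GDX replicate 3 and 0 without E2 replicate 2. Camera placed 20 of all 42 lists past its threshold, none of them with an estimated correlation, where 5 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.143, and fry placed 7. The fry adjusted p was 0.00367 for choroid plexus, 0.00679 for textbook estrogen-responsive genes and 0.00767 for arcuate genes. It was 0.0113 for neuropeptides and for the AVPV kisspeptin phenotype, and 0.0475 for peptide processing and for dopamine genes. With the covariate, camera calls were lost for the interferon (0.849), dopamine (0.336), glutamate (0.152) and oxidative phosphorylation (0.447) lists. Median or mean and the direction of camera also differed in sign for the potassium and HCN, insulin and IGF, clock, suprachiasmatic, GnRH neuron and microglial lists, none of which camera called.

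**Figure D3:**
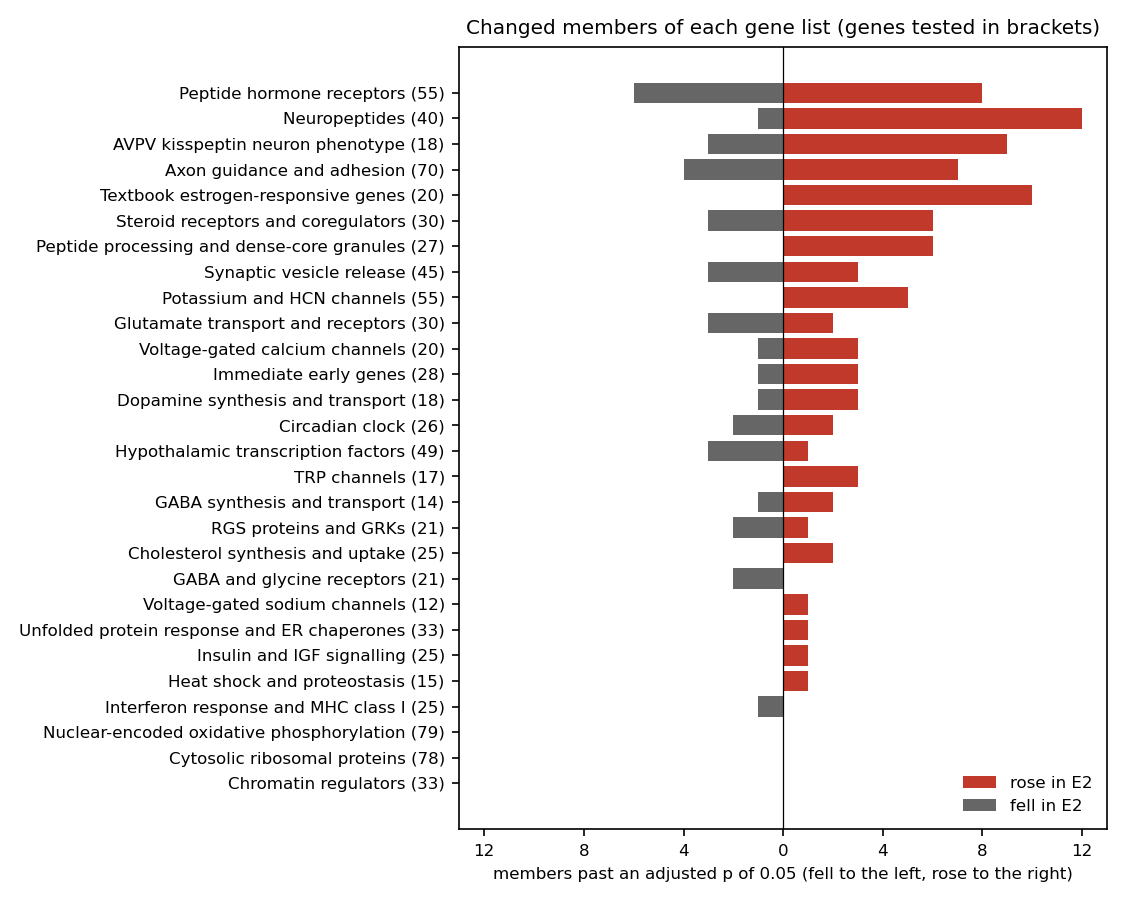
Number of tested members of each biology list that fell (to the left) and rose (to the right) in E2 against GDX by edgeR, with the number of genes tested in brackets. Neuropeptides have the most rises, 12 of 40 genes, and peptide hormone receptors have 8 rises beside 6 falls.

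Marker RNA of other cell types was lower in E2 for several types. The astrocyte list differed by −0.58 on the log2 scale (two-sided exact permutation p = 0.0857), the endothelial list by −0.85 (exact p = 0.114), the pericyte and fibroblast list by −0.98 (exact p = 0.143), and the ependymal and tanycyte list by −0.69 (exact p = 0.0571). The oligodendrocyte precursor list differed by −0.40 (exact p = 0.0571), the oligodendrocyte list by −0.29 (exact p = 0.429) and the microglial list by 0.03 (exact p = 0.8). Pan-neuronal markers differed by 0.15 (exact p = 0.0857), choroid plexus markers by 0.26 (exact p = 0.229), blood markers by 1.09 (exact p = 0.114) and nuclear-retained RNA by 0.47 (exact p = 0.143). Markers of the suprachiasmatic nucleus differed by 0.22 (exact p = 0.429), of GnRH neurons by −0.02 (exact p = 0.914) and of the arcuate nucleus by 0.71 (exact p = 0.0286). After adjustment over the 14 lists the lowest p was 0.222. With 1 library left out, differences moved to −0.41 for pericytes and fibroblasts, 0.07 for the suprachiasmatic nucleus and 0.20 for nuclear-retained RNA without GDX replicate 4, to 0.37 and 0.13 for the suprachiasmatic nucleus without E2 replicates 2 and 3, to −0.06 for oligodendrocytes without GDX replicate 1, and to 0.09 and −0.03 for choroid plexus without E2 replicates 2 and 3. Those of microglia and GnRH neurons, near 0, ranged from −0.07 to 0.10 and from −0.12 to 0.07. The astrocyte score was 6.99, 6.35, 6.33 and 7.12 in the 4 GDX libraries and 5.97, 6.13 and 6.23 in the 3 E2 libraries.

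No astrocyte, oligodendrocyte, precursor, microglial, endothelial, pericyte, blood or GnRH neuron marker gene changed by edgeR, and none among nuclear-retained RNAs, where DESeq2 called 5 astrocyte genes, 1 endothelial, 1 blood and 1 nuclear-retained gene and limma-voom none. At an unadjusted p under 0.05 edgeR gave 7 astrocyte, 8 endothelial, 4 pericyte, 3 blood, 2 precursor, 1 oligodendrocyte, 1 microglial and 1 nuclear-retained gene. Gfap, the astrocyte filament gene, was 939 ± 722 CPM in GDX and 182 ± 20.2 CPM in E2 (log2 fold change −2.36 ± 0.77, adjusted p = 0.218). In the ependymal list 2 genes fell, Cfap126 and Rarres2, or 9 genes adjusted over the list alone. Cfap126 and Rarres2 lost their calls without GDX replicate 1 (adjusted p = 0.07 and 0.1) or any E2 replicate (0.0778 to 0.1685 and 0.0834 to 0.117), and Cfap126 also without GDX replicate 3 (0.0624). In the choroid plexus list 3 rose, among them Ttr from 3.54 to 12.4 CPM and Enpp2 from 132 to 253 CPM. In the arcuate list Agrp, Ghsr and Ghrh rose and Tbx3 fell, where Ghrh lost its call without GDX replicate 1 (adjusted p = 0.0847), GDX replicate 2 (0.0675), E2 replicate 1 (0.102) or E2 replicate 3 (0.1245), and Tbx3 lost its call without any library but GDX replicate 3 (0.0599 to 0.184). In the suprachiasmatic list 3 rose and 1 fell, or 4 and 3 adjusted over the list alone, and 1 pan-neuronal gene rose. Camera adjusted p values were 0.000237 for astrocytes, 6.43e-05 for endothelium, 0.00413 for pericytes, 0.00014 for ependyma, 0.0363 for precursors and 0.0444 for oligodendrocytes, all lower in E2. They were 0.0267 for pan-neuronal, 0.00284 for choroid plexus, 0.00411 for blood, 0.000389 for arcuate and 0.0363 for nuclear-retained RNA, all higher. With an estimated correlation the adjusted p values of these 11 lists ranged from 0.143 to 0.779. With the non-neuronal covariate 9 of the 11 calls were lost: astrocytes (0.849), endothelium (0.572), pericytes (0.654), ependyma (0.114), precursors (0.572), oligodendrocytes (0.514), pan-neuronal (0.572), blood (0.188) and nuclear-retained RNA (0.711). The astrocyte, endothelial and oligodendrocyte markers are part of that score, so the covariate takes out their shift by construction. With 1 library left out, camera calls were lost for oligodendrocytes (GDX replicate 1, 0.484, and E2 replicates 2 and 3, 0.0744 and 0.132), precursors (GDX replicate 1, 0.171, and E2 replicate 2, 0.0828) and pan-neuronal markers (GDX replicates 1 and 4, 0.0503 and 0.0932, and E2 replicate 2, 0.0734). The call of nuclear-retained RNA was lost without GDX replicate 3 (0.0658) or 4 (0.0932) or E2 replicate 1 (0.0587) or 3 (0.0764), and the median log2 fold change turned negative for arcuate genes without E2 replicate 2 (−0.0482) and for choroid plexus genes without E2 replicate 3 (−0.188).

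**Figure D4:**
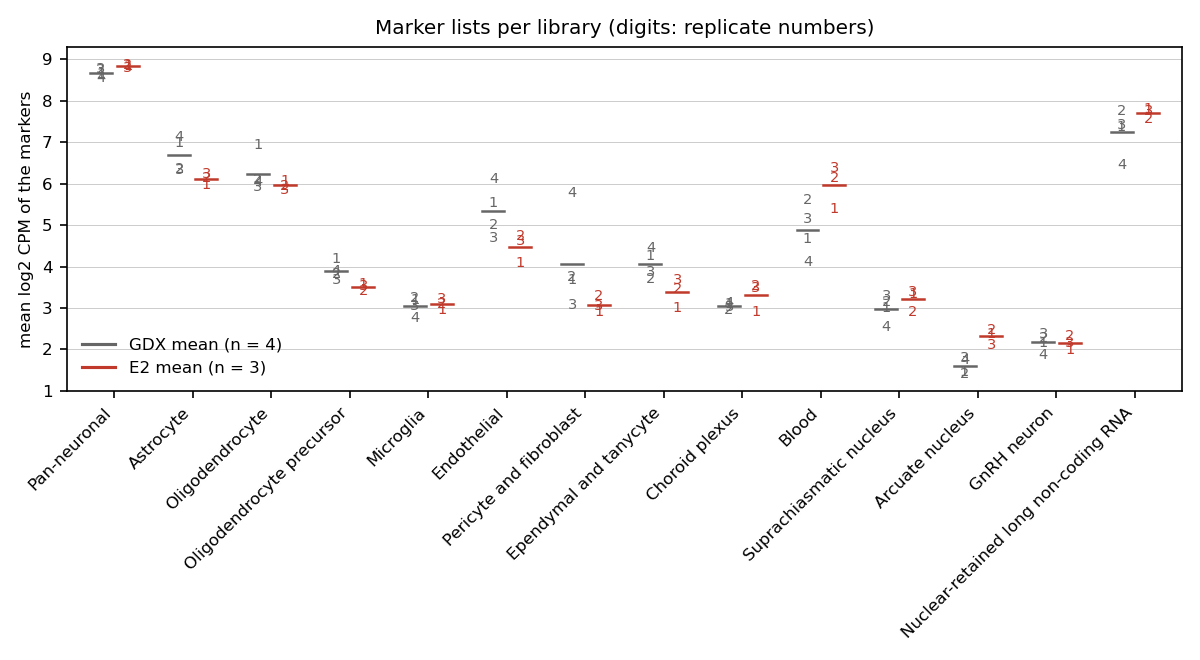
Mean log2 CPM of each marker list in the 4 GDX and 3 E2 libraries (digits are replicate numbers) with a bar at each group mean. GDX replicates 1 and 4 have the highest astrocyte scores, 6.99 and 7.12, and the highest endothelial scores, 5.54 and 6.11.

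Of the 100 named genes that changed, 63 kept their call in every one of the 7 fits that left out 1 library, and 60 kept it with the covariate, and no named gene that changed turned direction under any alternative. The named genes given above without a lost call kept it with each library left out.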

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

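The tests of arcuate RNA, of a separate preparation, of a shared shift of all other cell types (blood less endothelium and the 9 lists included) and of library-to-library variation were chosen only after the results were seen, and the 2 tests with the covariate were planned. In 192 groups of 4 GDX libraries, 15 had a library far from the others by Dixon's ratio, the gap to the nearest library over the whole range, where chance gives about 1 in 20 groups, or 9.6 of 192, and the library was GDX replicate 4 in 6 cases, 1 in 4, 2 in 3 and 3 in 2.

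Kiss1 stood at 113.5 CPM in GDX replicate 4 against 44.5 to 56.0 CPM in the other GDX libraries (ratio 0.834), and Gm28040 at 219 against 75.5 to 92.7 CPM. Arcuate kisspeptin neurons also make neurokinin B from Tac2, so their RNA would raise Tac2 in that library, and Tac2 was 29.96 CPM there, within the 26.67 to 40.14 CPM of the other GDX libraries, which argues against that source. A separate preparation may also account for it, since this is the 1 library whose label number lies outside the first 6, it held 0.656% of its counts in mitochondrial pseudogenes against 1.39% to 2.26% elsewhere, and with 1 such library the preparation and the library cannot be told apart. Without it, the summed counts of Kiss1 and Gm28040 gave a log2 fold change of 3.51 (adjusted p = 4.45e-12), within a range of adjusted p over the left-out libraries up to 0.0611. The design names no difference among GDX pools, so no biological explanation was tested.

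Astrocyte and endothelial marker RNA was lower in E2 and stood highest in GDX replicates 1 and 4. More non-neuronal RNA in GDX was examined with the marker score as a covariate. The median log2 fold change kept a share of 0.964 for called genes lower in E2 (−0.78 without and −0.751 with it). It kept 0.979 for called genes higher (0.69 and 0.67), with every gene on its side. Only 90 of 243 and 207 of 467 genes kept their call. The median standard error went from 0.132 to 0.169 and from 0.104 to 0.144, and a degree of freedom was lost. The score also did not overlap between the groups (5.06 to 5.73 in GDX, 4.83 to 5.04 in E2), so larger errors and lost calls were likely whatever the cause. For some genes the fold itself shrank (lower quartile of the share kept, 0.784 for genes lower and 0.856 for genes higher). The called changes thus mostly did not follow this score. Calling favours genes with little spread within groups. The score varied among the GDX libraries, so genes that follow it were less likely to be called. A high share was therefore likely beforehand, and the test cannot decide whether non-neuronal RNA was a cause. The score also holds no pericyte or ependymal markers. A lower share of tagged-cell RNA in GDX would shift all other cell types alike, and the endothelial score less the microglial score differed by −0.886 (exact permutation p = 0.114), and the blood score less the endothelial score, −2.0 to 0.61 in GDX and 1.31 to 1.76 in E2, differed by 1.94 (exact permutation p = 0.0857, as for the variance of the shifts of 9 lists), which goes against it without passing the threshold. Variation between pull-downs (astrocyte score, exact permutation p = 0.0857) and a response of those cells to estradiol, which was not tested, also stay open with 7 libraries.

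Ghsr, Agrp and Ghrh, on the list of arcuate genes, were higher in E2. For Ghsr, RNA of untagged arcuate cells in the E2 punches is argued against. Agrp, Npy and Pomc, abundant arcuate transcripts, were together higher by 4.11 CPM (SE 1.08), and Ghsr rose by 39.6 CPM. Tagged arcuate kisspeptin neurons, which the pull-down would enrich, stay open as a source, since these transcripts mark other arcuate neurons. For Agrp and Ghrh arcuate tissue may still be a source. Npy had a log2 fold change of 0.20 with an upper 95% limit of 1.01, where a rise equal to that of Agrp in CPM would need 1.24. The ratio of Npy to Agrp in such tissue is assumed, so the tissue and a response of the cells cannot be told apart. A response of the tagged cells to estradiol stays open as a hypothesis.

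Igfbp4 was 34.2 CPM in GDX replicate 4 and 10.1 to 14.2 in the other GDX libraries (ratio 0.831). Lepr was 7.15 CPM in GDX replicate 4 and 0.973 to 1.76 in the others (0.873). Igf1 was 6.81 CPM in GDX replicate 4 and 0.659 to 1.58 in the others (0.851). Igf2 was 237 CPM in GDX replicate 4 and 22.1 to 33.1 in the others (0.9485). Gabra2 was 170.2 CPM in GDX replicate 4 and 142 to 144 in the others (0.932). The pericyte and fibroblast score, which was not flagged, was 5.77 in GDX replicate 4 and 3.06 to 3.74 in the other GDX libraries. Whether these values share a source was not tested.

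Mbp was 2615 CPM in GDX replicate 1 and 1173 to 1314 in the other GDX libraries (0.902). The oligodendrocyte score was 6.92 in GDX replicate 1 and 5.92 to 6.09 in the others (0.831). Pcsk2 was 270.0 CPM in GDX replicate 1 and 326 to 335 in the others (0.853), and Slc17a7 was 1.91 against 1.04 to 1.09 (0.944). Agrp was 0.503 CPM in GDX replicate 2 and 0.192 to 0.218 in the others (0.917), Kiss1r was 9.73 against 5.17 to 5.91 (0.838), and the total was 29207544 counts against 35084629 to 36213127 (0.839). Cacng5 was 46.5 CPM in GDX replicate 3 and 41.1 to 41.3 in the others (0.952), and Scn1a was 41.8 against 54.4 to 54.9 (0.959).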

How the results depend on the processing

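Library sizes without scaling, GDX replicates 1 and 4 left out together and the summed Kiss1 locus were chosen only after the results were seen, and all other alternatives were planned. Genes higher in E2 numbered 467, and 722 without a filter, 710 with limma-voom, 221 with the non-neuronal covariate, 275 at an adjusted p under 0.01 and 268 to 591 with 1 library left out (268 without E2 replicate 1, 311 without E2 replicate 2). Genes lower numbered 243, and 887 without a filter, 725 with DESeq2, 399 with limma-voom, 94 with the covariate, 85 at 0.01 and 96 to 428 with 1 library left out (154 without GDX replicate 1, 428 without GDX replicate 3, and 96, 107 and 135 without E2 replicates 1, 2 and 3). List members changed numbered 108, and 174 without a filter, 55 with the covariate and 61 to 134 with 1 library left out (61 without E2 replicate 1, 71 without E2 replicate 3). Lists past camera's threshold numbered 20, and 13 with a mean of at least 5 CPM, 7 with the covariate, 10 without GDX replicates 1 and 4, 0 with an estimated correlation, 7 by fry and 13 to 19 with 1 library left out (13 without E2 replicate 2). The 0.01 threshold passes fewer genes by construction, and for all other settings, left-out libraries included, the cause was not tested.

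Kiss1 had a log2 fold change of 2.64 in all libraries, 3.04 with the covariate (adjusted p = 0.145, the highest of a range from 3.81e-10) and 2.49 to 3.03 with 1 library left out, where the call was lost without GDX replicate 1 (0.0575), E2 replicate 1 (0.0574) and E2 replicate 2 (0.0593). The direction of camera and the median both reversed for cytosolic ribosomal proteins (−0.103 with the covariate, −0.0747 without GDX replicates 1 and 4), nuclear-encoded oxidative phosphorylation (−0.0316 and −0.0159) and oligodendrocytes (0.129 with the covariate). The median changed sign, with the direction of camera kept, for arcuate genes (−0.0482 without E2 replicate 2), choroid plexus (−0.0564 without a filter, −0.188 without E2 replicate 3), dopamine genes (0.0168 with the stricter filter, 0.0227 without E2 replicate 1), peptide processing (−0.000844 with the covariate, where its call was lost) and glutamate genes (−0.0354 with library sizes alone, −0.0141 with the replicate block, and −0.0168, −0.0119 and −0.00758 without GDX replicate 4, E2 replicate 1 and E2 replicate 3). The oligodendrocyte markers are themselves part of the covariate score. The cause of these reversals was not tested.

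The 710 changed genes kept their direction under every setting that gave them a value (626 of 626 with the stricter filter), and 297 of them were called again with the covariate, 674 at an unadjusted p under 0.05. With library sizes alone 385 rose and 352 fell, with a median shift of all genes of −0.06. Pairing by replicate number was not seen: deviations from the group mean correlated at −0.02, −0.038 and −0.055 between libraries of the same number, and 0 of 6 libraries correlated best with its own number. With the number as a block, in which GDX replicate 4 has no partner, 421 rose and 191 fell, 519 of the 710 genes among them, 16 lists passed and Kiss1 had a log2 fold change of 3.02. At the floor of 3 counts, levels under 0.101 CPM were not detectable in the smallest library.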

Other observations

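The tests of X-linked genes and of gene pairs over 10 kb apart were chosen only after the results were seen, and the test of neighbouring genes and the counts over splits were planned. The genes in the next 2 paragraphs lie outside the naming rule and were chosen after their values were seen. Several abundant genes changed. Tmem35a, a chaperone gene of nicotinic receptors on the X chromosome, rose from 58.0 to 252 CPM (log2 fold change 2.12 ± 0.09, adjusted p = 1.74e-07). Syt6, of the synaptotagmin family, rose from 60.2 to 218 CPM, Crtac1 from 72.8 to 220 CPM (adjusted p = 1.31e-07), and Ezr, which links actin to the membrane, from 59.1 to 165 CPM. Zcchc12 fell from 1561 to 802 CPM (log2 fold change −0.96, adjusted p = 0.000134) and the imprinted gene Peg10 from 610.0 to 303 CPM (−1.01, 3.02e-05). The neuroglobin gene Ngb fell from 190.5 to 99.5 CPM, and the interleukin receptor gene Il13ra1 from 71.0 to 30.0 CPM.

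Some genes changed that had low levels in 1 of the groups. Npy4r, a receptor of the neuropeptide Y family, rose from 0.337 to 5.86 CPM (adjusted p = 0.000442), Fam19a4 rose from 0.587 to 6.38 CPM, and Edar fell from 3.04 to 0.483 CPM. Fam151a had 0, 0, 0 and 6 counts in the GDX libraries, under the floor in 3 of 4, and 217, 142 and 184 in the E2 libraries (adjusted p = 0.000598). Dbh, which makes noradrenaline from dopamine, had 0, 0, 0 and 9 counts in the GDX libraries and 119, 80 and 98 in the E2 libraries (log2 fold change 5.55, adjusted p = 0.01). Its call was lost without E2 replicate 1 (log2 fold change 5.44, adjusted p = 0.0563) and with the covariate (6.85, 0.1251). With 1 library left out its log2 fold change ranged from 5.14 to 9.70, so the size of the rise is uncertain.

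The count of splits goes against chance for changed genes and changed list members, at a share of 0.0286, the smallest that 35 splits can give. It cannot exclude chance, and the count of lists, at the same share, is less clear. The other splits mix E2 and GDX libraries, which can raise their spread within groups and lower their counts. Only 1 of 35 splits of the 7 libraries, the real one, gave as many genes higher (467, highest other 1), genes lower (243, highest other 4), list members changed (108, highest other 0) and lists past camera's threshold (20, highest other 18). For lists, other splits came close to the real one, also with 17 lists when GDX replicates 1, 2 and 4, or 1, 3 and 4, were set against the rest.

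Changed genes may be more frequent on the X chromosome, as a hypothesis: 45 of 629 X-linked genes (7.15%) and 665 of 17621 autosomal genes (3.77%) changed, an odds ratio of 1.96 with a 95% interval of 1.4 to 2.69 (two-sided Fisher's exact p = 8.53e-05). Of the X-linked genes 26 rose and 19 fell. Matched for expression level in 20 bins the odds ratio was 1.87, and over the alternatives it ranged from 1.4 to 2.36. Genes are not independent of each other, so this p overstates the certainty.

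Neighbouring genes may change together, tested among protein-coding genes of the autosomes and the X chromosome. Of 10675 adjacent pairs of non-overlapping tested genes within 100 kb, 30 changed in the same direction and 4 in opposite directions. Shuffled calls gave a mean of 12 same-direction pairs (95% range 6 to 19, one-sided permutation p = 1e-04, the smallest that 10000 shuffles can give). Calls were shuffled without matching for expression level, so the permutation p values may overstate the certainty. Pairs over 10 kb apart numbered 20 against a shuffled mean of 6.31 (one-sided permutation p = 1e-04). Reads running up to 10 kb past the end of one gene into the next are thus argued against as the whole cause. Longer runs stay open, since these pairs had gaps from 10278 to 93926 bp and the test did not use the orientation of the genes.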
